A study of Skeletonema costatum with 9 samples.

How the data were processed

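RNA was measured in 9 samples of the marine diatom Skeletonema costatum, carrying the strain label CCMA-130, with 3 libraries in each of the groups LC, GC and HC. Per the labels' protocols, cells grown in 12 h light and 12 h dark were collected on day 100, polyadenylated RNA was enriched, and the libraries were sequenced on an Illumina HiSeq instrument. The labels give the group codes without spelling them out. LC served as the reference because the series text sets GC and HC beside a wild type, although the genotype label of all 9 libraries is wild type. The replicate numbers come from the titles. Nothing in the labels says that the replicates of a group were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

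The deposited table holds FPKM (fragment abundance scaled to transcript length and to library size) for 57991 transcripts in the 9 libraries. Its identifiers have the form that the assembler Trinity writes and end in the name of a library, read here as the library whose assembly gave the contig. Per the submitters' processing notes, Bowtie2 2.2.5, RSEM 1.2.8 and DESeq were used, with no role given for any of them. How the assemblies were merged, which contigs were removed and how fragments with several matches were shared are not given in the sources used here. The 57991 transcripts belong to 47956 Trinity genes counted separately for each assembly, so several identifiers may stand for the same gene, and fragments may be split between them. No identifier carries a gene name (0 of 57991), and no annotation was used here. The 33 gene lists fixed before the data were examined were therefore not tested, and transcripts are named by identifier alone.

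Absolute depth is unknown. Relative depth was read from the steps of low values: a transcript with a few fragments in each of a pair of libraries gives a ratio of FPKM set by the numbers of fragments sequenced. The most frequent log2 ratio among transcripts at 0.15 to 0.6 FPKM in both libraries (558 to 1361 transcripts per pair, kernel width 0.03) was taken for each of the 36 pairs and averaged per library. The pairwise values closed to within 0.015 at the median and 0.064 at most on the log2 scale. No interval that needs a fragment count could be given. A value of 0 in such a table can also be a failed estimate, so transcripts are described as listed at 0, with no fold change against a group that has a library at 0.

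Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, using a group-means model of all 9 libraries and moderated tests with an intensity trend and robust variance estimates. Only the 45276 transcripts with a mean of at least 1 FPKM over the 9 libraries were tested, which left out 12715. A transcript was called at a Benjamini-Hochberg adjusted p below 0.05 within its comparison. Fold changes are on the log2(FPKM + 1) scale and understate the change of transcripts with low values. The comparisons were GC against LC, HC against LC and HC against GC, plus an F test of all 3 groups together. The contrast of HC against GC is also the test of whether the differences of HC and GC from LC differ. These designs, most alternatives and the rule for named transcripts were fixed before the data were examined. By that rule, the 2 called transcripts with the largest rise and the 2 with the largest fall in each comparison are named, among those at or above the median level whose libraries do not overlap between the groups. Overlaps between comparisons that share the LC libraries were set beside 20 simulated draws with unchanged groups. Single values per library were compared with exact permutation tests, two-sided, whose smallest p with 3 libraries against 3 is 0.1. Identical libraries were looked for, and the highest share of equal values in any pair was 21.2%.

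The test was tried on simulated data of 45276 transcripts with 200 changed in HC. Among 45076 unchanged transcripts it made 1 false call in HC against LC, 1 in HC against GC and 0 in GC against LC. In HC against LC it recovered 14 of 100 transcripts changed 4-fold and 0 of 100 changed 2-fold at the adjusted threshold, and 64 and 57 of them at an unadjusted p below 0.05. In HC against GC it recovered 15 and 1 at the adjusted threshold. With so few changed transcripts the adjustment is severe, so a transcript that was not called may still differ.

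Alternatives were quantile normalization, median-centred log2 values, no filter on low values, a mean of at least 5 FPKM, a pseudocount of 0.1, the replicate number as a block, only the 2 groups compared, stricter thresholds, and each library left out in turn. Alternatives chosen after the data were seen were sums per Trinity gene, equal library totals, limma without trend and robust estimates, only transcripts above 0 in all libraries, only transcripts assembled from the group outside the comparison, counts of detected transcripts by the group of assembly and without 2 sets of transcripts, and the test without those 2 sets, which are described in the results. They were also defined after the data were seen. For the shared profile, transcripts at 30 FPKM or more in HC, with a log2 ratio of HC to LC from 4.5 to 6.5 and above 0 in all libraries, gave a median profile over the 9 libraries, refined over transcripts within a root mean square of 0.5. Tested transcripts within 0.5 of it on the log2(FPKM + 1) scale, with a fitted HC level of at least 3 FPKM, were its members. Values, exact tests and figures were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.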

Results

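The transcriptome of the diatom Skeletonema costatum was measured in 3 groups of 3 libraries, LC, GC and HC, in a series whose title concerns ocean acidification. Abundance was given as FPKM for 57991 assembled transcripts, and the summed FPKM per library lay between 1001900 and 1090110. The relative number of fragments ranged from 89.8% to 104% of that in LC1, with group means of 94.0% for LC, 94.9% for GC and 101% for HC. A total of 31463 transcripts had a value above 0 in all 9 libraries.

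The HC libraries stood apart from the LC and GC libraries. Across the 45276 tested transcripts, which are not independent of each other, log2(FPKM + 1) correlated within groups with r from 0.843 to 0.877. Between LC and GC libraries r was 0.813 to 0.861, against 0.591 to 0.717 between LC and HC and 0.647 to 0.75 between GC and HC. The first principal component carried 46.1% of the variance and separated HC from the other libraries, and the component after it, with 11.9%, separated LC from GC.

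**Figure D1:**
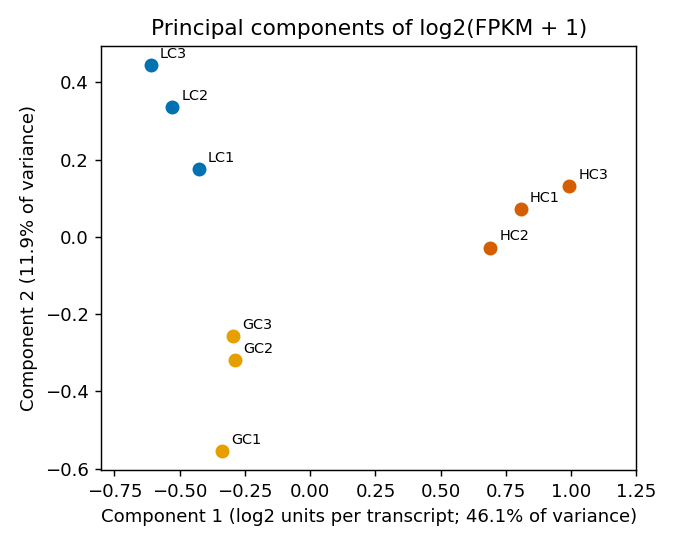
Principal components of log2(FPKM + 1) over the tested transcripts, with component 1 (46.1% of variance) on the horizontal axis and component 2 (11.9%) on the vertical axis, in log2 units per transcript. Each point is 1 library, coloured by group: HC lies at 0.69 to 0.99 on component 1, and LC and GC lie below 0 there and on opposite sides of 0 on component 2.

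The number of transcripts detected was highest in HC, from which more contigs had been assembled (22757) than from GC (18066) or LC (17168). At 1 FPKM or more, 39816 ± 925 transcripts were found in HC, 36322 ± 902 in GC and 35320 ± 392 in LC (SD, n = 3). The exact permutation p was 0.1 for HC against LC and for HC against GC, the smallest that 3 libraries against 3 allow, and 0.2 for GC against LC. In both comparisons with HC the order was the reverse among contigs from the group outside the comparison: 11595 ± 741 of the GC contigs were detected in HC and 12679 ± 195 in LC, and 10444 ± 556 of the LC contigs in HC and 12014 ± 263 in GC (SD, n = 3; exact permutation p = 0.1 for both). The group outside is not neutral, because LC and GC libraries correlated more with each other (mean r 0.837) than with HC (0.662 for LC, 0.711 for GC). Its contigs may thus favour the other group over HC, so the reversed order does not separate choice of contigs from real differences. The 100 most abundant transcripts, ranked by mean FPKM over all 9 libraries, held 20.9% ± 1.09 of all FPKM in HC. They held 24.9% ± 1.49 in GC and 26.9% ± 1.18 in LC (SD, n = 3). The exact permutation p was 0.1 for HC against either group and 0.3 for GC against LC. Most of the ranked libraries were LC or GC, which favours transcripts high there. The shares therefore do not measure how concentrated expression was within HC. In the joint F test of the 3 groups, 16894 transcripts (37.3% of those tested) changed, and 10658 did so without HC3.

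GC against LC asked how the GC cells differed from the reference. In this comparison 1322 transcripts rose and 861 fell, 2183 in all or 4.82% of those tested. Among the 100 most abundant transcripts, 3 rose, 7 fell and 90 were not called. After quantile normalization 3 rose and 3 fell, and with median-centred values 1 rose and 7 fell. The called transcripts together held 12.1% of the FPKM in LC and 11.0% in GC. The largest rises were in TRINITY_DN1934_c0_g1_i1-GC3 and TRINITY_DN6908_c0_g1_i1-GC3. The former had 938 ± 319 FPKM in GC and 3.36 ± 3.79 in LC (SD, n = 3), a log2 change of 8.07 (SE 0.59, limma adjusted p = 0.00150), and stood at 80.9, 166 and 157 FPKM in HC1, HC2 and HC3. The latter had 495 ± 194 FPKM in GC and 1.40 ± 1.75 in LC (log2 change 7.86, SE 0.53, limma adjusted p = 0.00145). The largest falls were in TRINITY_DN4676_c1_g1_i1-LC3 and TRINITY_DN13126_c0_g1_i1-LC1. The former fell from 61.1, 47.7 and 360 FPKM in LC1, LC2 and LC3 to 0.88 ± 0.52 (SD, n = 3) in GC, with a limma adjusted p of 0.00824. The latter had 39.7, 15.9 and 179 FPKM in the LC libraries and 0.77 and 0.25 in GC1 and GC3, and was listed at 0 in GC2 and in every HC library (limma adjusted p = 0.0136).

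Of the calls in GC against LC, 1300 were at least 2-fold, 765 of them higher and 535 lower. The split by direction depended on the scaling of the libraries. Rising transcripts made up 60.6% of the calls as deposited, 50.5% after quantile normalization (923 higher, 905 lower) and 43.7% with median-centred values (794 higher, 1023 lower). The number of calls also depended on single libraries: it was 370 without GC1, 504 without LC3, 929 without GC2, 1029 without HC1, 1126 without LC2, 1342 without HC2 and 1396 without HC3, and 248 in a test of only the 6 LC and GC libraries.

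HC against LC asked how the HC cells differed from the reference, and it gave the largest of the 3 counts. Here 11313 transcripts rose and 5934 fell, 17247 in all or 38.1% of those tested, and 12143 of them changed at least 2-fold. The direction was the opposite among the 100 most abundant transcripts: 14 rose and 44 fell, and of those 7 rose and 34 fell at least 2-fold. The ranking used the mean over all libraries, most of them LC or GC, which by itself favours falls in HC. Among those 100, falls also outnumbered rises after quantile normalization (26 rose, 33 fell) and with median-centred values (7 rose, 54 fell). Among the 1000 most abundant, 300 rose and 278 fell as deposited, 302 and 279 after quantile normalization, and 184 and 386 with median-centred values. The called transcripts held 53.1% of the FPKM in LC and 52.0% in HC. The largest rises were in TRINITY_DN21356_c2_g1_i1-HC3 and TRINITY_DN6559_c0_g2_i1-HC2. The former had 7448, 1423 and 19289 FPKM in HC1, HC2 and HC3 and 17.4, 4.57 and 1.43 in LC1, LC2 and LC3 (log2 change 9.87, SE 1.11, limma adjusted p = 0.000334), with 26.0, 23.2 and 127 FPKM in GC1, GC2 and GC3. The latter had 957 ± 161 FPKM in HC (SD, n = 3), 0.23 and 0.56 FPKM in LC2 and LC3, and was listed at 0 in LC1 and in the 3 GC libraries (limma adjusted p = 6.34e-07). The largest falls were in TRINITY_DN9053_c0_g1_i1-LC1 and TRINITY_DN673_c0_g1_i1-LC2. The former had 352, 228 and 98.9 FPKM in LC1, LC2 and LC3 and was listed at 0 in every HC library (limma adjusted p = 7.37e-05). The latter had 400 ± 283 FPKM in LC and 1.93 ± 0.56 in HC (SD, n = 3; log2 change −6.90, SE 0.40, limma adjusted p = 2.32e-05), and 35.1, 31.8 and 36.1 FPKM in GC1, GC2 and GC3.

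The median log2 change over all tested transcripts in HC against LC was 0.18 as deposited, −0.04 after quantile normalization and −0.13 with median-centred values. Rising transcripts made up 65.6% of the calls as deposited, 49.0% after quantile normalization (8485 higher, 8839 lower) and 45.2% with median-centred values (7814 higher, 9473 lower). A mean of at least 5 FPKM left 9807 calls among 20887 transcripts.

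HC against GC tests whether HC and GC differed from LC by different amounts. In it 7511 transcripts rose and 4702 fell, 12213 in all or 27.0% of those tested. Falls again outnumbered rises among the abundant transcripts, whose ranking favours falls in HC here too. Of the 100 most abundant, 40 were lower in HC and 8 higher, and of the 1000 most abundant, 230 were lower and 146 higher. This order held after quantile normalization (32 lower and 16 higher, 239 and 150) and with median-centred values (49 and 2, 294 and 95). The largest rises were in TRINITY_DN6559_c0_g2_i1-HC2 (limma adjusted p = 4.86e-07), already named, and TRINITY_DN21750_c0_g1_i1-HC3. The latter had 404 ± 175 FPKM in HC (SD, n = 3), was listed at 0 in every GC library, LC1 and LC3, and stood at 0.15 FPKM in LC2 (limma adjusted p = 1.87e-06). The largest falls were in TRINITY_DN9053_c0_g1_i1-LC1, with 238, 49.5 and 170 FPKM in GC1, GC2 and GC3, and TRINITY_DN12378_c0_g1_i1-LC3, with 42.8, 107 and 184. Both were listed at 0 in the 3 HC libraries (limma adjusted p = 0.000178 and 0.000135).

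As in the other comparisons, the split of the HC against GC calls moved with scaling. Rising transcripts made up 61.5% as deposited, 47.5% after quantile normalization (6228 higher, 6874 lower) and 45.8% with median-centred values (5906 higher, 6979 lower). There were 6991 calls without HC3, 7786 without HC1 and 6150 at a mean of at least 5 FPKM.

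A total of 1028 transcripts were higher in both than in LC, and 688 were lower in both. Simulated unchanged groups, with the LC libraries redrawn too and shared by both comparisons, gave 0.1 and 0.2 such transcripts on average over 20 draws. Independent lists of these sizes would give 330 and 113. Unchanged groups give almost no calls, so the simulated counts leave out the effects of either group. The covariance of the log2 changes was 0.461, against 0.126 in the simulation, a difference of 0.335. Their correlation across transcripts was 0.455, against 0.503 in the simulation. Sharing the LC libraries gives that simulated value without any effect, so the difference between these correlations does not measure a shared response. The 3 LC libraries are too few to be split into sets of 2 or more each, so part of the excess may come from the shared controls. Transcripts higher in both numbered 138 without GC1, 202 without LC3, 402 without HC1, 478 without GC2, 493 without LC2, 553 without HC2, 570 without HC3 and 663 after quantile normalization. Those lower in both numbered 156 without GC1, 195 without LC3, 275 without GC2, 390 without HC1 and 415 without LC2.

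Most transcripts with a graded or group-specific pattern set HC apart. HC was above both other groups for 6696 transcripts and below both for 3301, while GC was above both for 235 and below both for 155. These counts include 2 sets, described below, that were chosen for high levels in HC. In HC against GC, 2379 rises came from the shared-profile set and 394 from other transcripts present in HC alone. The remaining transcripts gave 4738 rises and 4702 falls there. Of all 7511 rises in HC against GC, 6069 were in contigs from HC. A stepwise rise, from LC to GC and again from GC to HC, was called for 257 transcripts and a stepwise fall for 226. In 49 transcripts GC and HC differed from LC in opposite directions, with 24 higher in GC and lower in HC and 25 the reverse. Independent lists of these sizes would give more.

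**Figure D2:**
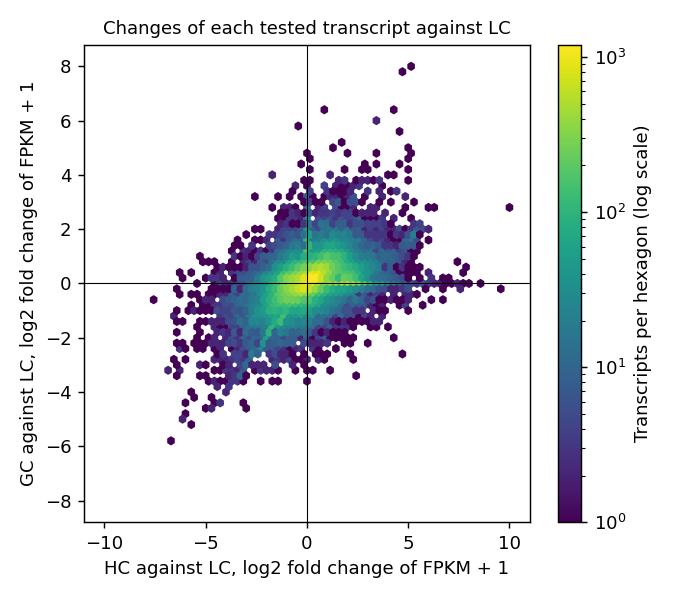
Log2 changes of FPKM + 1 against LC for each tested transcript, with HC on the horizontal axis and GC on the vertical axis; colour gives the number of transcripts per hexagon on a log scale. The cloud is tilted upwards (correlation 0.455 across transcripts) and is wider along the HC axis. Simulated unchanged groups gave 0.503, which comes from the simulated LC libraries that both changes share.

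The direction of the calls followed the library from whose assembly the transcript came. Among transcripts assembled from HC, 7841 rose and 429 fell in HC against LC, with a median log2 change of 1.1. Among those assembled from LC, 1035 rose and 3636 fell, with a median of −0.42. Transcripts assembled from GC, the group outside that comparison, had a median of 0.00, with 2437 rising and 1869 falling, a split that turned to 1507 and 3072 after quantile normalization and to 1211 and 3207 with median-centred values. The HC contigs kept their majority of rises under both scalings (6334 against 726, and 6145 against 865), and the LC contigs their majority of falls (5041 against 644, and 5401 against 458). In GC against LC, the transcripts assembled from GC rose 724 times and fell 101 times, and those assembled from LC rose 127 times and fell 648 times. The HC against GC calls split into 6069 higher and 380 lower among transcripts assembled from HC, and 699 higher and 2243 lower among those from GC. Tested alone, the transcripts assembled from the group outside the comparison gave 235 calls of 16486 in GC against LC (181 higher, 54 lower, against 471 and 112 in the test of all transcripts), 3820 of 14876 in HC against LC (2211 higher, 1609 lower, against 2437 and 1869) and 2303 of 13914 in HC against GC (576 higher, 1727 lower, against 743 and 2079). In HC against GC the majority of calls was thus in the opposite direction to that among all transcripts as deposited. LC libraries correlated more with GC (mean r 0.837) than with HC (0.662), so the choice of LC contigs may by itself favour GC over HC. Each named transcript came from a library of the group in which it was higher, except the pair that fell in HC against GC, which came from LC libraries.

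**Figure D3:**
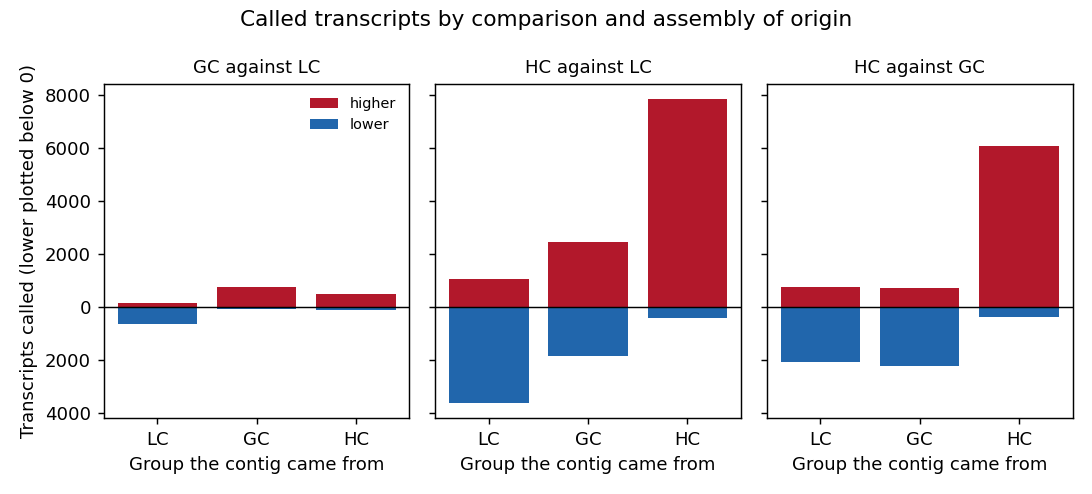
Number of transcripts called in each comparison, split by the group whose library gave the contig; red bars above 0 count transcripts higher in the group named first and blue bars below 0 count those lower. In HC against LC the contigs from HC rose 7841 times and fell 429 times, whereas those from LC rose 1035 times and fell 3636 times.

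A set of transcripts abundant in HC kept nearly fixed ratios over the 9 libraries. Of the 169 transcripts that were at 30 FPKM or more in HC, above 0 in all libraries and 4.5 to 6.5 log2 units higher in HC than in LC, 108 lay within 0.5 log2 units of a shared profile. Relative to the HC mean, this profile stood at 2.17%, 1.71% and 2.25% in LC1, LC2 and LC3, at 9.73%, 3.61% and 14.1% in GC1, GC2 and GC3, and at 80.9%, 89.2% and 139% in HC1, HC2 and HC3. In all, 2410 tested transcripts followed it, but at low fitted levels the profile lies so near 0 in LC and GC that values of 0 there also pass. The 297 with a fitted level of at least 10 FPKM were better resolved, although the profile may still put them near 0 in LC. Of the 2410, 2393 were assembled from HC. Their share of all FPKM was 0.053% to 0.066% in the LC libraries, 0.27%, 0.11% and 0.39% in GC1, GC2 and GC3, and 2.52%, 2.80% and 4.01% in HC1, HC2 and HC3. They made up 2409 of the 11313 rises in HC against LC, 2379 of the 7511 in HC against GC and 34 of the 1322 in GC against LC. That nearly all were called in the comparisons with HC follows largely from the rule that chose them.

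**Figure D4:**
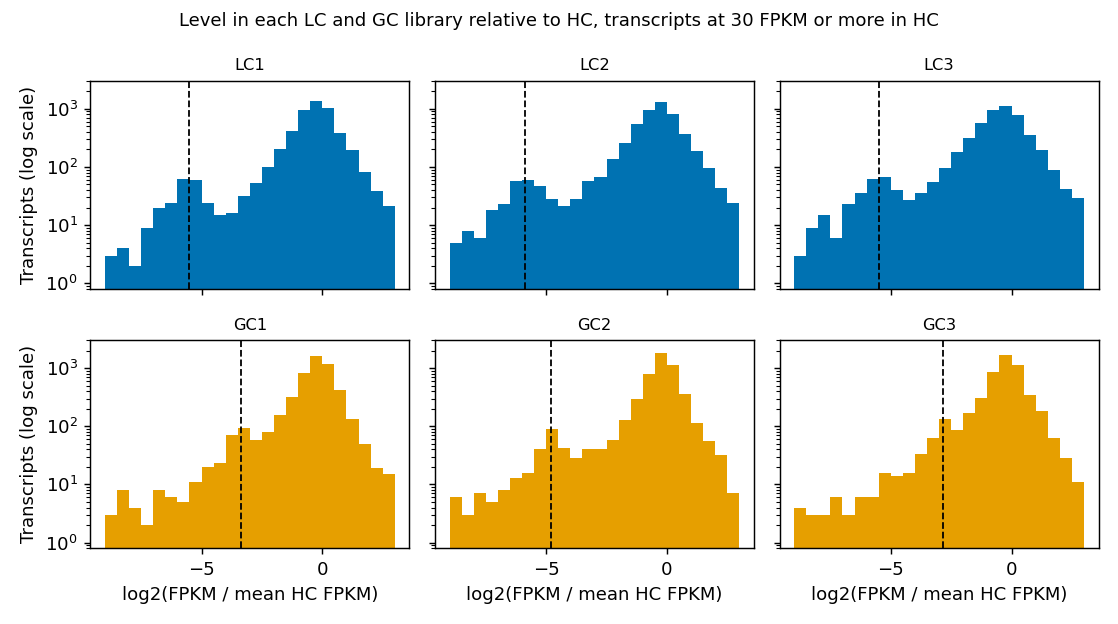
Distribution of log2(FPKM divided by mean HC FPKM) in each LC and GC library, for transcripts at 30 FPKM or more in HC and above 0 in that library; bars count transcripts on a log scale in bins of 0.5. The main mode lies near 0, and dashed lines mark the shared profile, near −5.5 in LC1, −5.9 in LC2, −5.5 in LC3, −3.4 in GC1, −4.8 in GC2 and −2.8 in GC3.

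Another set of transcripts was present in HC alone. At 1 FPKM or more in the 3 libraries of a group and listed at 0 in the other 6, there were 1461 transcripts in HC, 36 in LC and 22 in GC. The HC set had a median of 3.58 FPKM and a maximum of 217, with 123 transcripts at 10 FPKM or more, and held 0.70% to 0.88% of the FPKM of the HC libraries. Of these transcripts, 1453 were assembled from HC and 535 also met the rule for members of the shared profile. Listed at 0 in every LC and GC library, these 535 show no ratio there, so the rule cannot tell membership from absence. Of the 930 abundant enough to test, 929 were called higher in HC against LC and 929 in HC against GC, which follows largely from the rule that chose them. Without this set and the profile set, HC against LC gave 13618 calls (8072 higher, 5546 lower), HC against GC 8214 (4141 higher, 4073 lower) and GC against LC 2292 (1380 higher, 912 lower). Without them, 36494 ± 931 transcripts were at 1 FPKM or more in HC, 35938 ± 717 in GC and 35201 ± 399 in LC (SD, n = 3), with an exact permutation p of 0.1 for HC against LC, 0.6 for HC against GC and 0.2 for GC against LC. Both sets were chosen for high levels in HC, and no set chosen for low levels in HC was left out. Fewer rises and fewer detected transcripts in HC therefore follow largely from that choice.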

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

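All tests of explanations in this part, the counts of splits included, were written after the results they bear on had been seen.

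Drawing attention because GC and HC moved away from LC in opposite directions, 49 transcripts were called in both comparisons with opposite signs. All 49 were called in HC against GC too, but being chosen for opposite calls largely fixes that outcome. The 1461 transcripts present in HC alone drew attention because LC and GC had so few of their own; they were chosen by their levels in the groups compared, so no test of them in HC against GC is independent of that choice.

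For the transcripts on the shared profile, carry-over of reads from the HC libraries is argued against, because 97 of the 5247 transcripts at 30 FPKM or more in HC lay more than 2 log2 units below the profile's level in each of the 3 GC libraries. A candidate explanation is RNA of another organism or cell population, mixed in at a share that differs between libraries. Transcripts at 30 FPKM or more in HC and above 0 in every GC library were chosen by their ratio of HC to LC. They also shared a ratio between GC replicates, with a median log2 GC3 over GC2 of 1.81 (interquartile range 1.39 to 2.04, 180 transcripts), against 0.008 (−0.17 to 0.16) in 3500 abundant transcripts that did not differ between HC and LC. Transcripts listed at 0 in a GC library were left out, so the GC libraries had a part in the choice. Common regulation within the diatom, with the HC treatment as a biological cause, cannot be told apart from this. A single regulator could also give fixed ratios. The interquartile range of log2 GC3 over GC2 was 0.647, against 0.478 in 1003 other transcripts raised in HC, 757 of them less than 4-fold. By log2 ratio of HC to LC, it was 0.437 at 1 to 2, 0.631 at 2 to 3 and 0.993 at 3 to 4. It was 2.40 at 4 to 5, 0.490 at 5 to 6 and 0.597 at 6 to 7. No sequence or annotation was used here that could name the source.

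For the transcripts present in HC alone, an effect of assembling contigs from the same libraries that acted alike in every group would give LC and GC sets of like size. Those came to 58 together against 1461, which argues against such an effect. An effect that depends on the distance between groups is not excluded, since LC and GC libraries resembled each other. HC also gave more contigs (22757, against 17168 from LC and 18066 from GC). Isoforms or sequence variants of transcripts present in every library could be looked for only within the assembly of the same library. Of the 1453 in the set that were assembled from HC, 2.55% had such a transcript in their Trinity component. The share was 34.6% for other transcripts assembled from HC at like levels. This argues against isoforms from the same assembly, but variants of contigs kept from another library's assembly could not be seen and stay open. Missed detection of shared-profile members may account for part of the 123 at 10 FPKM or more and cannot be told apart from absence there: 10.9% of 2191 HC contigs at the GC3 level that the profile gives were listed at 0 in GC3, and with at most 689 members seen there this rate allows at most 84.0 missed ones, a ceiling for GC3 alone that lies below 123 by less than the 3-fold margin asked, while the 123 were listed at 0 in all 6 LC and GC libraries. It stays open too for the 1338 under 10 FPKM, whose median the profile puts at 0.476 FPKM in GC3, where 21.2% of HC contigs were listed at 0. A response to the HC treatment and RNA from another source in the HC samples both stay open and untested.

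The link between the direction of calls and the library of assembly may come in part from the choice of contigs: each of the 9 libraries exceeded its own replicates in the transcripts assembled from it, by a median log2 of 0.132 to 0.522, whereas in transcripts assembled from other groups the medians were −0.049 to 0.033. Without the shared-profile and HC-alone sets the excess was 0.15 to 0.378, with HC3 highest in both cases, so part of the HC3 excess went with those sets. Sequence match, selection of contigs where they scored highest and real differences between replicates were not separated. Calls against the origin ran opposite to what a choice of contigs where they scored highest would give: in HC against LC 1035 LC contigs rose and 429 HC contigs fell (644 and 726 after quantile normalization, 458 and 865 with median-centred values). They were not separated from false calls or from fragments split between several identifiers of the same gene. GC contigs, from neither group compared, gave 3820 calls, with a median log2 change of 0.00. However, GC libraries correlated more with LC (mean r 0.837) than with HC (0.711). The choice of GC contigs may thus favour LC over HC, so these calls do not separate it from real differences. For calls in the direction of the origin, real group differences and the choice of contigs cannot be told apart, because both act the same way there.

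Other splits of the libraries were counted for each number of calls. With 10 splits of 6 libraries a share below 0.05 is out of reach. The real split was the only 1 of the 10 to give as many calls in each comparison, with 2183 against at most 80 in the others for GC against LC, 17247 against at most 7 for HC against LC, and 12213 against at most 11 for HC against GC. In the joint test of the 3 groups, 1 of 100 splits, the real split itself, gave 16894 calls. This argues against a chance split of these 9 libraries. It cannot exclude chance differences between cultures, because the replicates of a group may be technical. The highest other count, 11571, came from a split that kept the 3 HC libraries together. The 3 other splits of that kind gave 8840 to 11571 calls and the 96 that parted the HC libraries gave 0 to 272, so most of the joint count rests on the distance of HC from the rest.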

How the results depend on the processing

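With median-centred values the majority of calls turned from rises to falls in the 3 comparisons, and the median log2 change over all tested transcripts turned from 0.18 to −0.13 in HC against LC, 0.05 to −0.14 in HC against GC and 0.08 to −0.03 in GC against LC. Quantile normalization turned both in HC against LC (median −0.04) and HC against GC (−0.08), and left GC against LC with a median of 0.00 and a majority of rises. With equal library totals rises stayed in the majority, at 64.7% in HC against LC, 58.8% in HC against GC and 64.7% in GC against LC, with medians of 0.15, 0.01 and 0.10. No named transcript changed direction under the alternatives run for it. Alternatives the processing account names as chosen after the data were seen were unplanned. Of the 232 alternative values for the 12 named results, 231 kept their direction and their call. TRINITY_DN13126_c0_g1_i1-LC1 was no longer called in GC against LC when only those 2 groups were tested (limma adjusted p = 0.0564). The rule that named these transcripts, by the largest called changes without overlap between groups, largely fixes this. Leaving out a library of the group outside the comparison cannot change the fold change. The count in GC against LC (2183) fell to 248 with only the 2 groups, 1300 with at least 2-fold changes, 154 at an adjusted p below 0.01, 1042 without trend and robust estimates, and 235 among transcripts assembled from HC. The count in HC against LC (17247) fell to 9807 at a mean of at least 5 FPKM, 10634 at an adjusted p below 0.01 and 3820 among transcripts assembled from GC. The count in HC against GC (12213) fell to 6150, 6411 and, among transcripts assembled from LC, 2303. The joint count (16894) was 9862 at a mean of at least 5 FPKM. Fewer transcripts were tested under the stricter filter and by origin. By origin this explains the fall only to 583, 4306 and 2822, the calls for the same contigs when all were tested; the other causes were not tested. The difference in detected transcripts turned among LC contigs to −1011 for GC minus LC, −2581 for HC minus LC and −1570 for HC minus GC, and among GC contigs to −1084 for HC minus LC and −2313 for HC minus GC. Transcripts higher in GC and HC than in LC (1028) numbered 663 after quantile normalization. Of the calls in GC against LC, HC against LC and HC against GC, quantile normalization kept 78.0%, 83.4% and 89.2%, median-centred values 75.6%, 79.7% and 86.9%, no filter 69.9%, 96.3% and 95.7%, a pseudocount of 0.1 at least 93.3%, and a mean of at least 5 FPKM, with fewer tested, 81.5%, 54.8% and 49.4%, none with another sign.

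Leaving out each library in turn gave 370 to 2601 calls in GC against LC, 11688 to 17696 in HC against LC, 6991 to 12849 in HC against GC and 10658 to 17378 in the joint test, lowest without GC1, HC3, HC3 and HC3. It gave 138 to 1450 transcripts higher in both groups and 156 to 740 lower in both, lowest without GC1, and a covariance of 0.446 to 0.636, highest without LC1.

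The replicate numbers did not pair the libraries: deviations from the group means correlated at −0.069 to 0.021 for the 9 pairs with the same number, against −0.061 to 0.075 for the 18 others, and 1 of 9 libraries correlated best with its own number. With the replicate number as a block, there were 826 calls in GC against LC, 15132 in HC against LC, 9872 in HC against GC and 13789 in the joint test, keeping 35.5%, 85.9% and 79.0% of the 3 sets of calls.

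Tests and size factors made for counts (DESeq2, limma-voom, RLE and upper-quartile factors) were not run because the values are FPKM, and the alternatives for gene lists were not run because no identifier carried a name. Absolute depth is unknown, which limits what a value listed at 0 can show.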

Other observations

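All values in this part were looked at only after the data had been seen.

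Transcripts missing from HC alone were also more frequent than those missing from another group. At 1 FPKM or more in 6 libraries and listed at 0 in the 3 of a group, there were 171 transcripts for HC, 12 for LC and 11 for GC. This is the reverse of the set present in HC alone, and no explanation for it was tested.

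The shared profile differed between replicates of a group. Only transcripts above 0 in every GC library were counted here. For 122 transcripts at 30 FPKM or more in HC with a log2 ratio of HC to LC from 5 to 6, the median log2 GC1 over GC2 was 1.42 (interquartile range 1.06 to 1.66) and the median log2 HC3 over HC2 was 0.62 (0.44 to 0.72). For 61 transcripts with a ratio from 3 to 4 the same medians were 0.22 (−0.39 to 0.79) and 0.07 (−0.30 to 0.38).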
